A study of Drosophila melanogaster with 3 samples.

How the data were processed

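Drosophila melanogaster embryos aged 0 to 24 h, of mixed sex, from a line with a C-terminal GFP fusion to CG3281 were used for ChIP-seq with an anti-GFP antibody on sonicated chromatin, per the labels' protocols. All 3 samples are biological replicates of 1 group by their labels. Libraries of a control input entered the authors' region calling and are not analysed here, and no untagged line was used here.

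Per the labels, each replicate's list of regions was called by the authors from its alignments and 1 control, a pooled list from all replicates, and the IDR set was derived from the replicate lists and the pooled list. These lists were made on 2 assemblies, dm6 and dm3. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited signal column holds the authors' signal value per region, whose scale differs between lists: the median signal was 33.9, 38.7 and 43.8 in replicates 1, 2 and 3 and 98.3 in the pooled list. A deposited −log10 q-value ranged from 3.42 to 4.06 in the dm6 IDR set. The deposited summit offset gives the position of the summit within each region. The lists are long by design: 30000 regions each, background included. The 6565 peaks of the IDR set were the 6565 strongest regions of the pooled list, so the set amounts to a threshold on the pooled signal, 198.3 at its lowest. The median width was 436 bp, the set covers 1.65% of the arms, and 77 peaks repeat the interval of another with a different summit. No depth or read count can be had from these lists, and intervals on shares cover counting error over genes or peaks only.

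Coordinates are dm6, given 1-based. Gene models came from the Ensembl release 115 annotation of the same assembly, with 13945 protein-coding genes and 19607 TSSs on 2L, 2R, 3L, 3R, 4 and X, and sequence from the RefSeq assembly of the same release. Chromosome names and arm lengths were compared, and every peak ends within its arm. The dm3 lists were used only for counts and replicate overlap, as no dm3 genome was used here. Of the names in the gene lists, 5 had a newer symbol and were matched to it: Z4 to pzg, calypso to caly, panx to Panx, h to hry and nos to nanos.

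Calculations were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9. A gene was bound when a summit lay within 500 bp of one of its TSSs. Chance positions came from 1000 circular shifts of the summits along each arm, for which the smallest two-sided p is 0.002. Summits were classed in the order promoter, 5' UTR, 3' UTR, coding exon, intron, intergenic. Shares of genes were compared by Fisher's exact test, peaks per arm by the exact binomial test, and motifs at the summit against a flank chosen at random on 1 side by the exact McNemar test, all two-sided, with Benjamini-Hochberg adjustment over the 23 lists, the 6 arms or the 13 motifs and a threshold of 0.05. Motif windows reached 50 bp to either side of the summit, and flanks were centred 500 bp away. Ratios for motifs and words were taken after 0.5 was added to both counts, so they can differ from the ratio of the printed shares. The window of an unbound promoter was centred at the median summit distance, -93 bp. Values for a named peak in a replicate came from the strongest region of that replicate's list that spans the pooled summit. Values over replicates are mean ± SD over the 6565 strongest regions of each list.

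The genes named are those at the strongest promoter peaks (the first 25 genes), up to 4 members with the strongest peaks per list, CG3281 and the 10 strongest peaks; some single genes that this rule gives are not reported. The gene lists, motifs, tests, naming rule and most alternative settings (other TSS windows, the stronger 3282 peaks, other overlap rules, each replicate left out, other backgrounds and assemblies) were fixed before the data were examined. For peak sets, leaving out a replicate meant keeping only the reproducible peaks matched among the strongest 6565 regions of both other replicates. Peaks were not called again. Alternatives chosen after seeing the data were dinucleotide-shuffled windows, local moves of summits, nearest-TSS assignment, splits by divergent neighbour and promoters with TSSs on 1 strand. With simulated random summits, 6565 in number, promoter share was 1.03 times chance and 0 lists passed. Unlike the real peaks, these summits were not rich in promoters, so this does not show how often lists pass with promoter-rich peaks. A list planted at -90 bp from its TSSs was recovered at 100% of its genes, which its construction ensures and which only checks the code.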

Results

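CG3281 is a Drosophila melanogaster gene for a C2H2 zinc finger protein. Its binding to chromatin was measured by ChIP-seq with an anti-GFP antibody in whole embryos aged 0 to 24 h, from a transgenic line that carries CG3281 fused to GFP. The series holds 3 biological replicates of 1 group, CG3281-GFP embryo ChIP, and no second condition, so the comparisons are between peaks and chance positions, between groups of genes and between replicates. Each replicate's list holds 30000 regions, ranked by the authors' signal value, and a list from the pooled replicates has the same length. The authors' reproducible set, filtered by the irreproducible discovery rate (IDR), holds 6565 peaks on the dm6 assembly and 6152 on dm3. Read depth is unknown, because peak lists give no read counts.

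The question of where the tagged protein was found was answered first by the strongest peaks. The highest pooled signal, 7908, lay on 2L from 6612387 to 6613000, inside an intron of CG11050. It was followed by a peak of signal 7304 on 3L from 19909902 to 19910617, between Mi-2, which encodes a chromatin remodelling ATPase, and Prp3, which encodes a splicing factor; the summit was at -10 bp from the Prp3 TSS. Next came an intergenic peak of signal 7244 on X from 12750822 to 12751700, whose nearest TSS, that of CG4004, was 5003 bp away. The first peak ranked 4, 2 and 1 in the lists of replicates 1, 2 and 3, and stood at 68.4 ± 4.28 (SD, n = 3) times the median signal of each replicate's own list.

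Of the 10 strongest peaks, others at promoters were those of mRpL43 and CG30183 (2R, 23697666 to 23698300, signal 6828), Ugalt (X, 2703662 to 2704091, signal 6755), CG13630 and tok (3R, 24719238 to 24720054, signal 6726), CG14100 (3L, 19590409 to 19590848, signal 6380) and CG31729 (2L, 13296036 to 13296698, signal 5648). The others lay in introns of Trl, which encodes the GAGA factor (3L, 14759262 to 14759873, signal 6194), and of ush, which encodes a cofactor of GATA factors (2L, 480847 to 481307, signal 6049). Signals here and below are the authors' own values per peak and serve only to rank peaks within a list. Genes further down the ranking were apt at signal 5549, ACC and Nup44A, which overlap and have TSSs at the same peak, at 5274, Dtwd2 and CG1227 at 4694, and ATPsynO, a subunit of ATP synthase, at 4575. CG30020 followed at 4505, Abcd3 at 4446, mRpL41 at 4152, PNPase at 4119, and mRpS10 with Art3 at 4079. The Wnt receptor gene fz had a signal of 4035, the glycolytic gene Gapdh2 4023, CG31145 3989 and CG6254 3929. Relative to the median of each replicate's list, the mean over replicates was 63.5 ± 15.1 (SD, n = 3) at Mi-2 and Prp3, 59.3 ± 9.65 (SD, n = 3) at mRpL43 and CG30183, and 34.9 ± 1.87 (SD, n = 3) at Gapdh2.

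The tagged gene itself had a peak at its promoter. A transgene insertion can give signal at the tagged gene's own locus, and this was not separated from binding. CG3281 (FBgn0260741) lies on the minus strand of 3R from 11960883 to 11962805, and the peak from 11962710 to 11963145 had its summit at -123 bp from the TSS. This promoter is shared with aurA, which encodes a mitotic kinase and is transcribed the other way. The pooled signal was 635.9, rank 1332 of the 6565 peaks. In the replicates the region ranked 1653, 827 and 2298, with a signal of 5.48 ± 1.89 (SD, n = 3) times the list median. Within 2 kb of the gene the pooled list held 1 further region, outside the reproducible set, with a signal of 72.47.

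Replicates were compared by asking how many reproducible peaks each one found among its own strongest 6565 regions, with at least 50% of the peak's length covered. Replicate 1 held 80.4% of the peaks, replicate 2 80.4% and replicate 3 84.6%, a mean of 81.8% ± 2.48 (SD, n = 3). All 3 replicates held 59.4% of the peaks, or 3897, against a mean of 0.000442% over 1000 circular shifts (p = 0.002, two-sided permutation of positions, the smallest value these shifts can give). Only 65 peaks were in none. Among the 657 strongest peaks 93.5% were in every replicate, among the 657 weakest 3.35%. In between the share did not fall steadily: the 656 peaks below the strongest were at 75.6%, and the next groups of that size by signal at 82.0%, 89.5% and 89.0%. Each reproducible peak is also a region of the pooled list, which contains the same replicates, so these shares are not independent of the set. Compared directly, from 67.2% to 73.1% of the strongest 6565 regions of one replicate were among those of another. Across the 5957 peaks with a covering region in every replicate's list, Spearman's rho of the signal was 0.717 for replicates 1 and 2, 0.719 for 1 and 3, and 0.682 for 2 and 3. Peaks are not independent replicates.

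Peaks were scarce on chromosome 4. This chromosome, a small and largely heterochromatic chromosome, carried 19 peaks where its length gave 66.1, a ratio of 0.287 (exact binomial test, two-sided, adjusted p = 8.8e-11 over 6 arms). It held 238 peaks per 1000 protein-coding genes, against 434 on 2R, 454 on 3R, 460 on 2L, 508 on X and 517 on 3L. Its share of the strongest regions was 0.371% ± 0.072 (SD, n = 3) in the replicates and 0.289% in the reproducible set, with an exact 95% interval of 0.174% to 0.452%. The other arms had ratios of 1.06 (2L), 0.999 (2R), 1.03 (3L), 0.987 (3R) and 0.967 (X), and none passed the threshold. Measured against the share of TSSs in place of length, 3L was above (1.12, adjusted p = 2e-05) and 2R below (0.922, adjusted p = 0.0025), both by the exact binomial test.

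Promoters held 45.9% of the summits, 3012 of 6565, when a promoter was the 500 bp on either side of a protein-coding TSS. Shifted positions gave 11.4%, so promoters were 4.01 times more frequent than chance (p = 0.002, two-sided permutation of positions, the smallest value possible). The size of this excess depends on the setting. With local moves of 20 to 100 kb as chance positions, added after seeing the data, it was 3.26 times. By circular shifts it was 5.73 times with a TSS window of 250 bp and 2.75 times with 1000 bp. The strongest regions of the separate replicates gave 46.4% ± 1.7 (SD, n = 3). Coding exons outside promoters were nearly free of summits, with 15 or 0.228% against 13.3% by chance, and 3' UTRs held 1.16% against 5.13% (adjusted p = 0.0035 for both, permutation). Intergenic sequence held 14.3% against 30.1% (adjusted p = 0.0035, permutation). Introns held 37.9% of the summits, 2489, close to the 39.2% of shifted positions (adjusted p = 0.24, permutation). The 5' UTRs outside promoters held 35 summits (0.533% against 0.783%, adjusted p = 0.05, permutation). Each summit has 1 class, so the excess at promoters by itself lowers the shares of the other classes. Introns kept close to their chance share in spite of this, and held 2489 of the 3553 summits away from promoters. A moderate fall, as at 5' UTRs, need not be avoidance. Shares among summits away from promoters were not tested against chance.

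**Figure D1:**
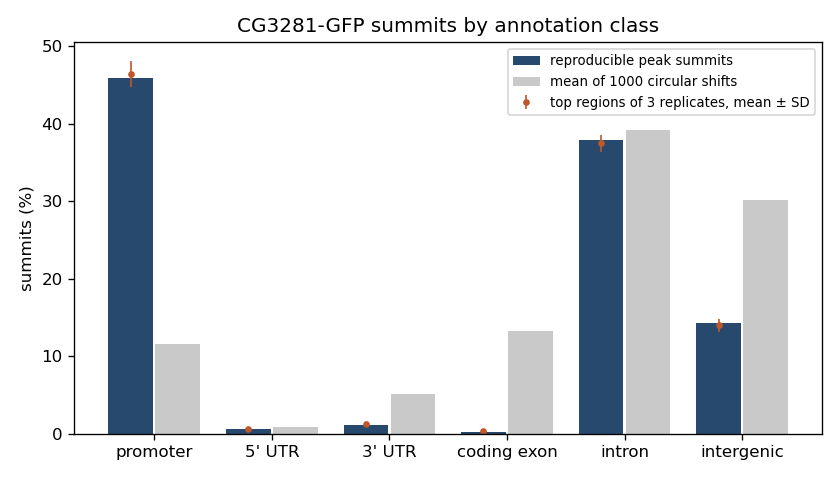
Share of summits (%, y axis) in each annotation class (x axis) for the 6565 reproducible peaks (dark bars) and for the mean of 1000 circular shifts (grey bars). Points with error bars are the mean ± SD of the strongest regions of 3 replicates. Promoters stood at 45.9% against 11.5% in the shifts made for this classification, and coding exons at 0.228% against 13.3%.

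Within promoters the summits lay upstream of the TSS. The median summit was at -93 bp, with quartiles at -194 and 8 bp, and 73.1% of summits (2195 of 3004 not exactly on a TSS, exact 95% interval 71.4% to 74.6%) were upstream (exact binomial test against even odds, two-sided, p = 2.8e-146). The median in the separate replicates was -93 ± 1.7 bp (SD, n = 3).

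**Figure D2:**
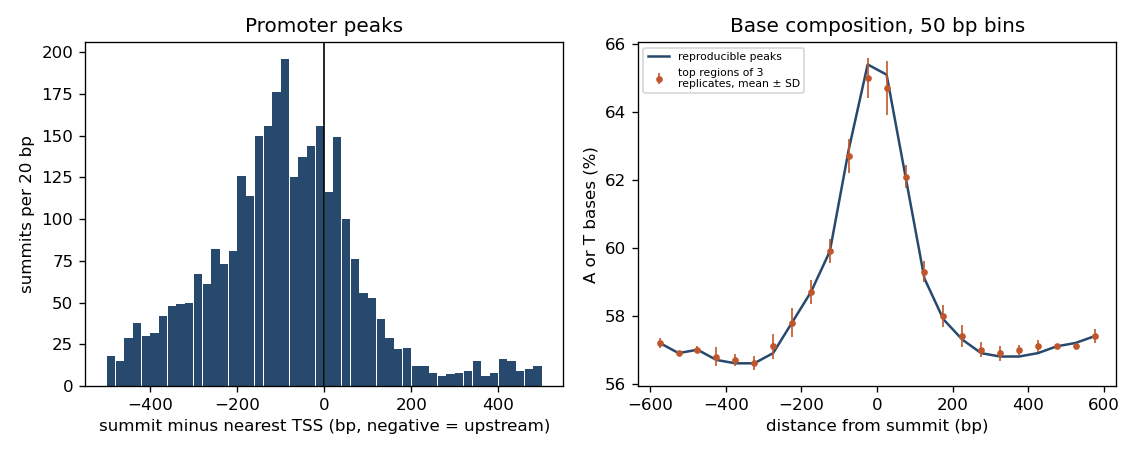
Left, number of summits per 20 bp (y axis) by distance from the nearest TSS in bp (x axis) for promoter peaks. Right, share of A or T bases (%, y axis, not starting at 0) in 50 bp bins by distance from the summit in bp (x axis), for the reproducible peaks (line) and for the strongest regions of 3 replicates (points, mean ± SD). Summits cluster at a median of -93 bp, and the AT share rises from about 57% in the flanks to 65.4% at the summit.

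Of 13945 protein-coding genes, 3456 (24.8%) had a summit within 500 bp of a TSS, and these are called bound below. Bound genes often stood back to back with another gene, as in the pairs Mi-2 and Prp3, mRpL43 and CG30183, or tok and CG13630. An opposite-strand TSS within 1000 bp upstream was present for 59.3% of bound genes (2050) and for 28.6% of unbound genes (3002 of 10489), an odds ratio of 3.64 (Fisher's exact test, two-sided, p = 1e-225). In the separate replicates the share among bound genes was 59.8% ± 1.8 (SD, n = 3). A single summit between both genes of a pair counts for both here; with each peak given only to the gene of the nearest TSS, the odds ratio was 1.84.

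Genes for the cytosolic ribosome were bound far more often than others: 77 of 85 (90.6%, exact 95% interval 82.3% to 95.8%) against 24.4% of all other genes, with an odds ratio of 29.9 (Fisher's exact test, two-sided, adjusted p = 1.4e-36 over 23 lists). Among the strongest were RpS27 (signal 2492, summit at -1 bp from the TSS), RpL7 (2016) and RpL14 (1751), and the median signal of the bound members was 766 against 411 for all bound genes. The separate replicates gave 88.2% ± 3.1 (SD, n = 3). The 8 members without a peak, looked up after the count was seen, included RpL21 and 6 genes that are 1 copy of a duplicated pair, RpL10Aa, RpS10a, RpS15Ab, RpS19b, RpS28a and RpS5b. For these 6 the other copy was bound: RpS10b at signal 1379, RpS28b at 997.3, RpS5a at 969.3, RpS19a at 873.5, RpS15Aa at 662.6 and RpL10Ab at 410.2.

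Genes for the mitochondrial ribosome were bound in 40 of 73 cases (54.8%, exact 95% interval 42.7% to 66.5%, against 24.6%, odds ratio 3.71, Fisher's exact test, adjusted p = 2.8e-07). They included genes at some of the strongest promoter peaks of all, mRpL43 (signal 6828), mRpL41 (4152), mRpS10 (4079) and mRpS23 (3917), though the median of the bound members was 353. The summit at mRpL43 (-170 bp) was nearer the TSS of CG30183 (-111 bp), and that at mRpS10 (-144 bp) nearer Art3 (-113 bp). Such peaks may belong to the partner gene, and the list was not tested with each peak given to the nearest TSS only. In the replicates the share was 48.9% ± 10 (SD, n = 3). With a divergent neighbour 39 of 58 were bound (67.2%), against 40.3% of other genes with one (odds ratio 3.04, Fisher's exact test, adjusted p = 0.00023). Without one 1 of 15 was bound, mRpL19 (6.67%, exact 95% interval 0.169% to 31.9%), against 15.8% of other such genes. The 2 parts of the list differed by Fisher's exact test (p = 2.3e-05). Cytosolic ribosomal protein genes were bound in 49 of 52 cases with a divergent neighbour and in 28 of 33 without (Fisher's exact test, p = 0.25).

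Other housekeeping lists did not stand apart from the 24.8% of all genes by Fisher's exact test. The complex I, proteasome and initiation factor lists went by symbol and include further copies without a peak, such as ND-20L, Prosalpha4T1 and eIF4E7. Respiratory complex I had 11 of 40 genes bound, with ND-ASHI at signal 1838 (exact test, adjusted p = 0.89). The proteasome had 13 of 48, led by Rpn3 at 640.6 and Rpn5 at 636.8 (exact test, adjusted p = 0.89), and the translation initiation factors 12 of 44, with eIF4EHP at 3721, eIF6 at 2937 and eIF1 at 1301 (adjusted p = 0.89). Cell cycle and replication genes had 11 of 33, among them CycE at 1216, dpa at 884.5, aurA at 635.9 and Mcm2 at 571 (exact test, adjusted p = 0.65). Heat shock genes had 6 of 15, with Hsp83 at 2687 and Hsp27 at 1862 (exact test, adjusted p = 0.52). Leaving out a replicate, by keeping only peaks matched in both others, is a stricter filter on the same set. It kept from 4399 to 4580 peaks and lowered the share of other genes to between 18.1% and 18.8%. The proteasome share then fell from 27.1% to 12.5% without replicate 2 and 16.7% without replicate 1 or replicate 3. The heat shock share fell from 40% to 20% without replicate 2 and 26.7% without replicate 1 or replicate 3. These falls do not show that the peaks depend on the replicate named.

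Genes of chromatin regulators were bound at shares above the average that did not pass the adjusted threshold. Architectural and insulator proteins had 9 of 19 (47.4%, Fisher's exact test, p = 0.032, adjusted p = 0.12), led by Chro (signal 3655), Cp190 (2158), Dref (1461) and M1BP (1252). Polycomb and trithorax group genes had 11 of 25 (44.0%, exact test, p = 0.035, adjusted p = 0.12), led by ph-p (3659), the remodeller gene brm (2455), escl (1297) and E(z) (1221). With genes closer than 1 kb merged into loci both passed the exact test, at adjusted p = 0.022 and p = 0.0014. A locus counted as bound when any gene in it was, so a member could take on a neighbour's peak. The shares rose to 52.9% and 56% in this way, and these passes do not show more peaks at the listed genes. The ZAD zinc finger genes, a family of related transcription factors, had 5 of 14 bound, among them M1BP, D19B at 760.2 and trem at 487.7 (exact test, adjusted p = 0.68), and heterochromatin and piRNA factors 7 of 17, with HP4 at 681.7 and cuff at 608.9 (adjusted p = 0.4). With the fewer peaks kept on leaving out replicate 1 or replicate 2, the ZAD share fell from 35.7% to 21.4%.

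Receptor, cuticle and histone genes were bound less often than others by Fisher's exact test. Of 179 odorant, gustatory and ionotropic receptor genes only Gr63a was bound, at a signal of 214.7 (0.559%, exact test, adjusted p = 5.2e-20). Only 10 of these receptor genes had any region of the pooled list at a TSS. Among genes with such a region the receptor share was 10% against 52.2% (exact test, adjusted p = 0.049). With genes closer than 1 kb merged into loci it was 4.05% against 23.3% (exact test, adjusted p = 5.3e-11). None of 120 cuticle protein genes was bound (exact test, adjusted p = 1.7e-14), although 23 of them had some region of the pooled list at a TSS. None of the 111 replication-dependent histone genes was bound (exact test, adjusted p = 1.3e-13), and the pooled list held no region at any of them; they are near-identical repeats, where reads often map to several places.

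Developmental and cell type genes were bound at shares that did not pass the threshold. Segmentation genes had 4 of 22, hry (signal 357.6), cad (276), nanos (271.4) and bcd (269.9), and dorsoventral genes 3 of 15, cact (948.3), rho (251.6) and dl (248.9). None of the 10 Hox genes and cofactors had a peak within 500 bp of a TSS (adjusted p = 0.38, Fisher's exact test), and the exact 95% interval reaches 30.8%. Among neuroblast genes insc (231.6) and SoxN (226.4) were bound, 2 of 15, and among neuronal genes elav (2632), Syx1A (365.6) and fne (279.1), 3 of 14. Muscle genes had 5 of 17, led by Msp300 (1485) and sls (558.1). Gut, fat body and hemocyte genes had 3 of 15, fkh (1768), Hnf4 (968) and GATAe (258.3). Germline genes had 4 of 11, led by bgcn (1043) and Sxl (914.8), and the Enhancer of split complex 2 of 11, E(spl)m3-HLH (1261) and E(spl)m7-HLH (217.4). Of the genes named by list, CycE, trem, bcd, rho, fne and E(spl)m7-HLH had a region spanning the summit in 2 of the 3 replicates' lists only. With the fewer peaks kept on leaving out a replicate, the segmentation share of 18.2% fell to 9.09% without replicate 1 or replicate 2. The Enhancer of split share of 18.2% fell to 9.09% without replicate 1 and 0% without replicate 2 or replicate 3. The neuroblast share of 13.3% fell to 6.67% without replicate 1 or replicate 2 and 0% without replicate 3.

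**Figure D3:**
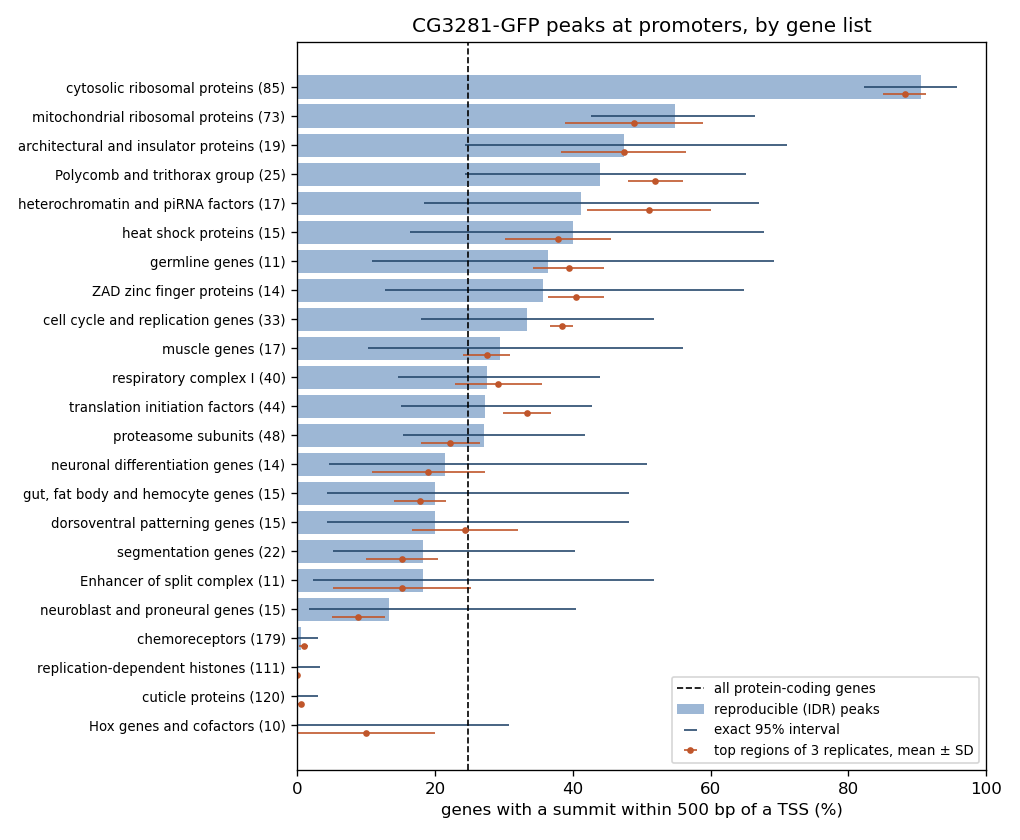
Share of genes with a summit within 500 bp of a TSS (%, x axis) for 23 gene lists (y axis, number of genes in brackets). Bars are the reproducible peaks with exact 95% intervals, points the mean ± SD of the strongest regions of 3 replicates, and the dashed line all protein-coding genes (24.8%). Cytosolic ribosomal proteins stand at 90.6%, while chemoreceptors, histones and cuticle proteins are at or near 0.

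Sequence at the summits was compared with flanks 500 bp away for 13 known Drosophila promoter and insulator motifs. The DRE, bound by Dref, was within 50 bp of 2.67% of summits against 1.21% of flanks (ratio 2.19, exact McNemar test, adjusted p = 1.1e-07). By the same exact test Ohler motif 7 was at 1.86% against 0.838% (ratio 2.21, adjusted p = 1.9e-06), the CTCF motif at 0.716% against 0.221% (3.17, adjusted p = 5.9e-05) and motif 1, bound by M1BP, at 0.427% against 0.0762% (5.18, adjusted p = 0.00036). GAGA repeats were rarer at summits, 1.19% against 2.69% (ratio 0.444, exact test, adjusted p = 5.8e-07). Across the replicates the ratio was 2.18 ± 0.3 for the DRE, 2.55 ± 0.18 for Ohler 7 and 0.554 ± 0.071 for GAGA (SD, n = 3). The TATA box (ratio 1.97), the E-box (2.42), Ohler 6 (2.64), the Su(Hw) motif (4.5) and the CGATA element of the BEAF-32 pair (1.2) also passed, 10 of 13 in all, while Inr (0.961), Ohler 8 (0.625) and Zelda (0.687) did not. Against dinucleotide-shuffled copies of the summit windows, added after seeing the data, 7 motifs passed by the exact McNemar test. GAGA was then more frequent at summits, 1.19% against 0.259% (ratio 4.49, exact test, adjusted p = 9.8e-11), the TATA box was at 2.21% against 2.18% (ratio 1.01), and Ohler 6 (1.93) and the Su(Hw) motif (1.8) did not pass.

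Motif 1, the E-box, Ohler 6 and the Su(Hw) motif lost the threshold under at least 1 other window, peak set or left-out replicate. Against unbound promoters, with windows all centred at the median summit distance from the TSS, only 3 motifs passed by Fisher's exact test. Windows of bound promoters were centred on their own summits, so the ratios of this comparison mix position with binding. Ohler 7 stayed higher at bound promoters (ratio 1.68, exact test, adjusted p = 0.00016) and GAGA lower (0.383, adjusted p = 3.2e-10), while Ohler 6 was lower (0.422, adjusted p = 0.024) after having been higher against flanks. The DRE was at 0.833 (exact test, adjusted p = 0.086).

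Words of 8 bases were searched on 2L, 3L and X and tested on 2R, 3R and 4. Against flanks the leading words were made of A and T: AATATTTA was at 5.09% of the 2811 held-out summits and 1.78% of flanks (ratio 2.84, exact McNemar test, p = 4.4e-10), and a matrix built from it matched 12.1% of held-out summits against 4.02% of left flanks. The summit windows held 65.3% A or T against 57.0% in flanks, and 64.9% ± 0.68 (SD, n = 3) in the replicates. For the 1363 held-out promoter peaks, set against unbound promoters, the leading word was CAACCCTG, at 1.69% against 0.187% (ratio 8.81, Fisher's exact test, adjusted p = 3e-09). CAGCCCTG was at 2.49% against 0.442% (ratio 5.62, exact test, adjusted p = 6.4e-10), AGCCCTGG at 1.69% against 0.255% (adjusted p = 4.9e-08) and CAACACTG at 2.64% against 0.714% (ratio 3.7, adjusted p = 7.2e-08). Of the 10 words found in this search 4 did not pass by the exact test on the held-out arms, AATTATTA (ratio 1.11, adjusted p = 0.62), ATATTTAA (1.33, adjusted p = 0.086), AATATACA (1.4, adjusted p = 0.21) and AATAATAT (1.3, adjusted p = 0.21). These words resemble each other and Ohler motif 7, whose pattern KNNCAKCNCTRNY was among the preset motifs (K is G or T, R is A or G). CAGCCCTG fits its core CAKCNCTR, and AGCCCTGG is that word moved by 1 base. CAACCCTG and CAACACTG depart from the core only at K. They are therefore not separate from the Ohler 7 result, and their overlap with its matches was not counted. No word here was present at more than a small share of the peaks.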

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

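The tests of neighbouring promoters, of summits counted for both genes, of high transcription, of other housekeeping genes and of dinucleotide composition were chosen after seeing the data; those of promoter composition, of library preparation and of close spacing were written once the peaks had been viewed but before their own results. In data outside the reproducible set, 235 of the 23435 remaining pooled regions were matched by the strongest 6565 regions of every replicate. They stood out because regions found in each replicate were left outside the set. Of these, 228 overlap a reproducible peak, so their signal is largely in the set already, and 7 do not. They add 6 bound genes to the 3456.

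Cytosolic ribosomal protein genes were bound in 77 of 85 cases. Peaks caught from neighbouring promoters do not account for this, since 84.8% of the genes without a divergent neighbour were bound (28 of 33) against 15.6% of other such genes. Housekeeping function, as far as these lists stand for it, does not either: the odds of being bound were 25.7 times those of complex I, proteasome and initiation factor genes, of which 36 of 132 were bound (Fisher's exact test, p = 2.6e-21). These lists went by symbol and hold further copies without a peak, such as ND-20L, Prosalpha4T1 and Prosbeta5R1. Such copies lower their share, and the comparison was not repeated without them. High transcription stays open, as 49 other genes chosen as abundantly transcribed from general knowledge were bound in 34 cases (69.4%, exact 95% interval 54.6% to 81.7%), far above the average, with an upper bound just short of the ribosomal lower bound of 82.3%. Set against them directly, ribosomal protein genes had 4.25 times the odds of being bound (Fisher's exact test, p = 0.0035), which goes against high transcription as the whole cause if both groups are transcribed alike, and that was not measured. The rule first set for this test, bounds that do not meet, would have excluded the explanation by this small margin; that the margin also exceed the spread of the list was required only after that result was seen. The genes were chosen after the peaks had been viewed, and some, among them Gapdh2, ATPsynO and Hsp83, were already known to be bound, which may raise their share. Signal at heavily transcribed genes may come with any tagged protein, and this cannot be told apart from binding without a mock precipitation or expression values, which were not used here. No other explanation was tested.

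Summits were rich in A and T. Promoter peaks were 3.37 percentage points richer than unbound promoters (63.9% against 60.6%). Peak windows were centred on their own summits, those of unbound promoters all at the median summit distance. The comparison mixes position with binding, so it cannot decide whether promoter composition accounts for the richness at promoters. Outside that test, summits away from promoters held 66.4% A or T against 58.4% in flanks. The composition of promoters therefore does not account for all of the richness. At the weakest 10000 regions of the pooled list the summit differed from the flanks by -0.184 points, against 8.23 in the reproducible set. This goes against a preference of library preparation or calling for AT-rich fragments that acts on all regions alike. The list includes background by design, so a preference limited to enriched regions cannot be excluded this way. Dinucleotide composition accounts for part of the leading word only: AATATTTA was 1.72 times as frequent at held-out summits as in shuffled windows (exact McNemar test, p = 3.5e-05). No biological explanation was tested.

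Bound genes often had a divergent neighbour. Counting 1 summit for both genes explains part, as the odds ratio fell from 3.64 to 1.84 with each peak given to the nearest TSS only (Fisher's exact test, p = 3.9e-43). Close spacing alone does not explain the rest: among genes with another gene's TSS within 1 kb, and again with each peak given to the nearest TSS only, divergent ones had 2.23 times the odds of being bound (24.9% against 13%, Fisher's exact test, p = 6.9e-17). No biological explanation was tested.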

How the results depend on the processing

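Of 446 values recomputed under another setting, 405 kept their side of the threshold, stayed within the replicate spread or, for counts, within 1.5 times. A change of direction was counted only where at least 1 of the 2 values passed the threshold. Shares that never passed could turn without being counted. The proteasome share, for example, was 27.1% against 24.8% of other genes, but 12.5% against 18.1% without replicate 2. The promoter share ranged from 36.1% to 55.9%, the divergent odds ratio from 1.84 to 3.84, the upstream share from 69.0% to 71.5%, and the cytosolic ribosomal share from 71.8% to 97.5%, all past the threshold under every alternative run. The stronger peaks by signal number 3282 by construction. Replicate agreement was 85.4% with any overlap, 86.4% for the top 1000 of each list and 96.5% with all regions. With TSS share as the expected value 3 arms passed in place of 1, 2R at 0.922 and 3L at 1.12. Polycomb and trithorax genes passed with a 250 bp window (44%), merged loci (56%) and among genes without a divergent neighbour (50%, added after seeing the data), and in 1 leave-one-out set, without replicate 2 (36% to 40% over these sets); architectural genes passed with merged loci (52.9%). Merged loci also count peaks at neighbours of the listed genes. Among genes without a divergent neighbour, the mitochondrial ribosomal share fell to 6.67% (Fisher's exact test, adjusted p = 0.81) and the histone share of 0% no longer passed, with few members left. Against unbound promoters 3 motifs passed in place of 10; there DRE was at 0.833, the TATA box 0.902, Ohler 6 0.422 and the BEAF-32 element 0.918, each below 1 in place of above. Against shuffled windows, added after seeing the data, GAGA passed at 4.49, above 1 in place of below, and the TATA box (1.01), Ohler 6 (1.93) and Su(Hw) (1.8) did not pass. Of 104 values of single motifs, 22 no longer passed and 2 newly passed. The cause was not tested in these cases. Histones with a pooled-region background and neuroblast genes with a divergent neighbour had no genes left. The dm3 chromosome test was not run, as no dm3 arm lengths were used here.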

Other observations

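All tests in this part were chosen after seeing the data, except the background of unbound promoters for words. Among annotated genes that do not code for proteins, tRNA genes carried summits within 500 bp of their start in 44 of 290 cases (15.2%, and 15.1% ± 2.6 over replicates, SD, n = 3) where shifted positions gave 4.55% (permutation of positions, adjusted p = 0.0033 over 5 classes). Other non-coding RNA genes had 270 of 3261 (8.28% against 4.58%, permutation, adjusted p = 0.0033). Shifted positions take no account of protein-coding promoters, which held 45.9% of summits. No value here sets apart non-coding genes that start near such a promoter. The excess at tRNA and other non-coding genes therefore need not be binding at these genes themselves. Annotated transposable elements had 74 of 5809 (1.27% against 4.28%, permutation, adjusted p = 0.0033), in repeats where reads can map to several places. By the same permutation small nucleolar RNA genes (24 of 269, adjusted p = 0.088) and small nuclear RNA genes (4 of 32, adjusted p = 0.19) did not pass.

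A scan of 109 families of gene symbols that share their leading letters, with at least 8 members each, goes by letters alone, so a family can hold unrelated genes. RpL genes were bound in 45 of 50 cases and RpS genes in 31 of 38 (Fisher's exact test, adjusted p = 2.6e-20 and p = 1.5e-11), mRpL in 25 of 47 and mRpS in 15 of 26. The family pre was also above average by the exact test (13 of 24, adjusted p = 0.027), and its bound members are pre-mod(mdg4) genes, several of which share a peak. Below average by the exact test were symbols in Cpr (1 of 71, adjusted p = 1.2e-06, the bound one being Cpr itself, which is not in the cuticle list), Or (0 of 59, adjusted p = 1.2e-06), Ir (0 of 60, adjusted p = 1.2e-06), Gr (1 of 60, adjusted p = 2e-05), Obp (2 of 51, adjusted p = 0.0014) and Cyp (7 of 85, adjusted p = 0.0014). Symbols in His were also below it (2.61% bound, exact test, adjusted p = 2.5e-09). Most of them are replication-dependent histone genes, at which the pooled list held no region. Those genes are near-identical repeats, where reads often map to several places. The His value therefore cannot show whether they were bound less often.

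The words CAACCCTG and CAGCCCTG differ at 1 base, and CAGCCCTG fits the core of the known Ohler motif 7, so they need not be a new element. They were joined after both had passed on 2R, 3R and 4, so counts on these arms are not a fresh test. On 2R, 3R and 4, which were not searched for words, either of them was within 50 bp of 55 of 1363 promoter summits (4.04%) against 0.11% of their flanks and 0.612% of unbound promoter windows. Away from promoters they were at 2 of 1448 summits on these arms (0.138% against 0.345% in flanks). Over all summits on these arms, at promoters or not, the share was 2.03%, and 1.8% ± 0.14 over the replicates (SD, n = 3). It was 2.58% in the 1393 stronger peaks and 1.48% in the 1418 weaker ones (Fisher's exact test, two-sided, p = 0.044). Among promoter peaks alone the values were 4.65% and 3.32% (exact test, p = 0.27). Over all arms, peaks with the word included those at Mi-2 and Prp3, tok, CG31729, apt, ACC and Nup44A, and ATPsynO.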
